A study of Mus musculus with 6 samples.

How the data were processed

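RNA from 6 samples of immortalized mouse proximal tubular cells was measured on an Illumina mouse bead array. The labels place 3 arrays in a control group, which received a short hairpin RNA against GFP, and 3 in a Glis2 knockdown group, which received one against Glis2. A short hairpin RNA is processed in the cell to a small RNA that lowers its target transcript. Per the labels, total RNA was extracted with Trizol, cleaned on a column with DNase treatment, checked on a Bioanalyser and hybridised with Cy3 label. The labels do not say whether the 3 samples of a group came from separate infections or cultures, so the p-values measure only the spread between these samples, which may be technical.

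The deposited table holds 1 linear intensity per probe and array. The software and the normalization that the authors used are not given in the sources used here. From the deposited values, the 6 arrays had already been brought to the same distribution, since their log2 medians differed by at most 0.00029 and their interquartile ranges by at most 0.024%. Background had not been subtracted: the lowest intensity was 85.4, the highest was 52227, and the most frequent value was 114. Scanner output and detection p-values were not used here. The number of arrays limits the precision.

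The values were floored at 16, which altered no value, and transformed to log2 without further normalization, as the rule fixed before the data were examined required. Of 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none. Of those with 1 symbol, 34807 were matched by Entrez identifier to a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. The build behind the array's design is not given in the sources used here, so that table served only for gene names, chromosomes and the order of neighbouring genes. Each of the 19057 genes was represented by its probe with the highest mean over the 6 arrays. Of 9172 genes with more than 1 probe, 32 had probes called in opposite directions.

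Knockdown was compared with control by limma 3.58.1 in R 4.3.3, with lmFit and eBayes without an intensity trend, and p-values were adjusted by Benjamini-Hochberg over all genes at a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 29 lists. The lists held 706 entries, of which 637 were measured, and covered cell states, signalling pathways and markers of other kidney cell types. The test, the lists, the rule for named genes and most alternatives were chosen before the data were examined. The named genes were Glis2, the 12 genes that rose and the 12 that fell most among called genes whose groups did not overlap, leaving out clone identifiers, and up to 4 called members of each list by smallest p.

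Tested on simulated data for the knockdown against control comparison with 19057 genes, the fit recovered 10% of genes changed by 0.25 on the log2 scale. It recovered 90% of those changed by 0.5 and 100% of those changed by 1 or 2. Only 50 genes were changed at each size, whereas limma called 22.5% of genes in the data. The adjustment is less strict when more genes change, so these shares need not hold in the data. Of its calls, 3.23% were unchanged genes. In a simulation on 9446 placed genes, the search for chromosome blocks found 1 of 1 planted block of 60 genes lowered by 0.4, and 0 blocks where none was planted. Genes varied independently there, and only the mitosis list was changed besides the block. Fold changes in the data spread more widely, with a shuffled limit of 0.389. The simulation therefore does not give the sensitivity or the rate of false blocks in the data.

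Several choices were made after the data had been seen. The background limit of 139 is the most frequent value plus 3 times the SD estimated from the values below it, and a gene was called above background when its mean over the 6 arrays exceeded that limit. A fold against a group whose 3 arrays all lay under the limit is given as at least N-fold, with the limit in place of those arrays. The chromosome pattern was first noticed with a slightly different limit and was then tested with windows of 25 genes against 1000 shuffled gene orders. Background subtraction, normexp correction, fold changes relative to 50 neighbouring genes and the removal of genes in chromosome blocks were added as alternatives at that stage. The search for gene families was run first over all genes and then over genes above background, and both outcomes are given. A first test of the X chromosome block used the genes that had defined it; it was replaced by a test on genes held out from that definition. A loess on intensity, tried first against an intensity trend, moved hardly any gene and was replaced by genes matched on intensity.

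Alternatives fixed beforehand were a replicate block, quantile normalization, median centring, a floor of 32, an offset of 50, filters on dim probes, eBayes with trend and robust settings, leaving out each array, the mean of a gene's probes, other thresholds, all probes, an estimated correlation in camera, and fry.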

Results

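Gene expression was compared between mouse proximal tubular cells with a stable knockdown of Glis2 and cells carrying a control hairpin against GFP, harvested 7 days after lentiviral infection, with 3 arrays per group. Glis2 encodes a Krüppel-like zinc finger protein of the Gli-similar family, and its loss is known to lead to cystic and fibrotic kidney disease. The comparison asks which transcripts differ between tubular cells with the Glis2 hairpin and those with the control hairpin. Effects of lowering Glis2 cannot be told apart here from other effects of the hairpin or from differences between the infected populations. On each array 39.7% to 39.8% of the probes lay above the background limit. Arrays correlated at r = 0.995 within groups and between 0.980 and 0.982 across groups, over 45281 probes that are not independent replicates.

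Glis2 itself was lower in the knockdown. The probe used for the gene, ILMN_1226316, had an intensity of 247 ± 26.4 in control and 169 ± 7.39 in knockdown cells (SD, n = 3 arrays each), a log2 fold change of -0.55 ± 0.092 (SE) with limma's adjusted p = 6.36e-05. A second probe, ILMN_2745305, went from 206 ± 13.6 to 161 ± 15.9, a log2 fold change of -0.36. On both probes all 3 knockdown arrays lay below all 3 control arrays. The design text gives a knockdown above 80%, by a measurement not analysed here, whereas the array means were 31.8% and 22.0% lower. Because background is included in these intensities, the reductions became 58.9% and 49.1% after the most frequent value of the arrays was subtracted, and the log2 fold change of the gene became -1.27 with limma's adjusted p = 0.0201, the highest of the alternatives run for Glis2, of which 5.26e-05 was the lowest. Normexp correction gave -0.88.

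**Figure D1:**
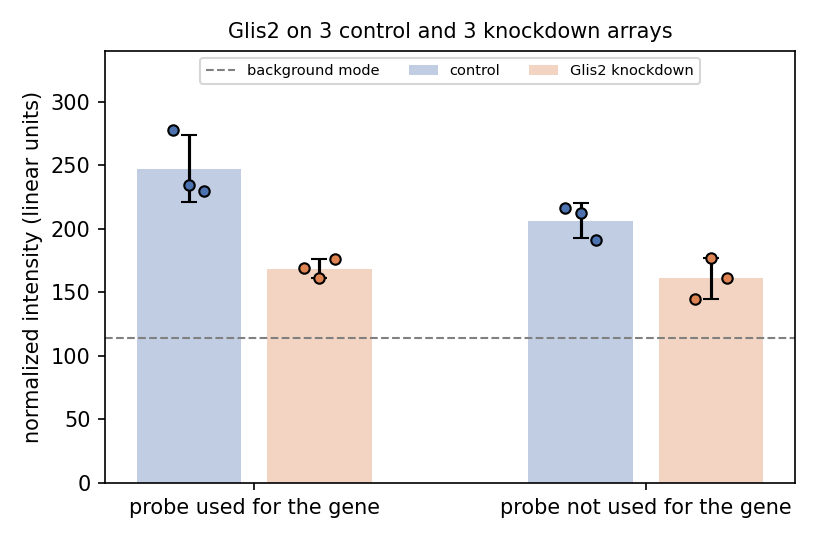
Glis2 intensity (linear units, y axis) for its 2 probes in control and knockdown cells; bars are means, error bars SD, points single arrays (3 per group), and the dashed line marks the most frequent intensity of 114. The knockdown means of 169 and 161 lie below the control means of 247 and 206 and remain above the dashed line.

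The genes that rose most included Hspb8, a small heat shock chaperone, which went from 173 ± 9.70 to 4198 ± 257, and Tnc, the matrix glycoprotein tenascin C, which went from 139 ± 7.59 to 3356 ± 368 (SD, n = 3). Their log2 fold changes were 4.60 ± 0.088 and 4.59 ± 0.093 (SE). Those that fell most were Mgp, the matrix Gla protein that inhibits calcification, from 6949 ± 1319 to 117 ± 12.6, and Aqp1, the water channel of the proximal tubule, from 9760 ± 706 to 365 ± 101. Mgp lay under the background limit on all 3 knockdown arrays and was at least 49.4-fold lower, and Aqp1 had a log2 fold change of -4.77 ± 0.13. In all, limma called 4290 of 19057 genes (22.5%), 2124 higher and 2166 lower in the knockdown, of which 189 at least doubled and 229 fell to no more than 50% of control. The groups did not overlap in 4140 of the called genes and in 32.2% of all genes, where chance gives 10%. Of the 9463 genes above background, 4142 were called. That share, rather than 22.5%, is the one to set beside the counts of gene lists below whose members lay mostly above background. With background subtracted the number of called genes was 2631, of which 424 at least doubled and 466 fell to no more than 50%, and with normexp correction it was 2566, with 331 and 372.

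Other genes among the 12 that rose most were the heparan sulfate sulfatase Sulf2 (log2 fold change 3.65), the caveolar coat protein Cavin2 (3.63), the endophilin Sh3gl2 (3.22) and the smooth muscle actin Acta2 (3.17), the last from 145 ± 24.6 to 1302 ± 172. The adhesion molecule Nectin3, the glutathione transferase Gstk1 and Xlr4a were under the background limit on all 3 control arrays and rose at least 10.2-fold, 10.01-fold and 7.70-fold. Prl2c2, Prl2c3 and Prl2c4 are near-identical proliferin genes whose probes may not tell them apart; the first 2 had log2 fold changes of 3.13 and 3.32, and Prl2c4 rose at least 7.50-fold. Tnc and Sh3gl2 were under the limit on 2 control arrays, and Prl2c3 and Acta2 on 1. The other probe of Sulf2 gave a log2 fold change of -0.22, and that gene rests on 1 probe. Where others of these 12 genes had further probes, those were dimmer and gave smaller changes than the probe used. Among the further probes, 2 of Sh3gl2 and 3 of Acta2 were called.

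Among the 12 that fell most, Mmp13, a collagenase, had a log2 fold change of -3.77, as did Masp1, a serine protease of the lectin pathway of complement. The receptor tyrosine kinase Axl fell from 7255 ± 293 to 878 ± 27, and ceruloplasmin, Cp, from 4968 ± 225 to 625 ± 62.1. Arginase 1, Arg1, had a log2 fold change of -3.26, the protease cathepsin C, Ctsc, one of -2.87, and Itm2a, Tns4 and Glipr1 had -3.95, -3.31 and -3.12. Megf10, an engulfment receptor, had -3.16 and lies on chromosome 18 among neighbouring genes that were also lower. Second probes of Itm2a and Axl had mean intensities of 107 and 124, under the background limit.

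**Figure D2:**
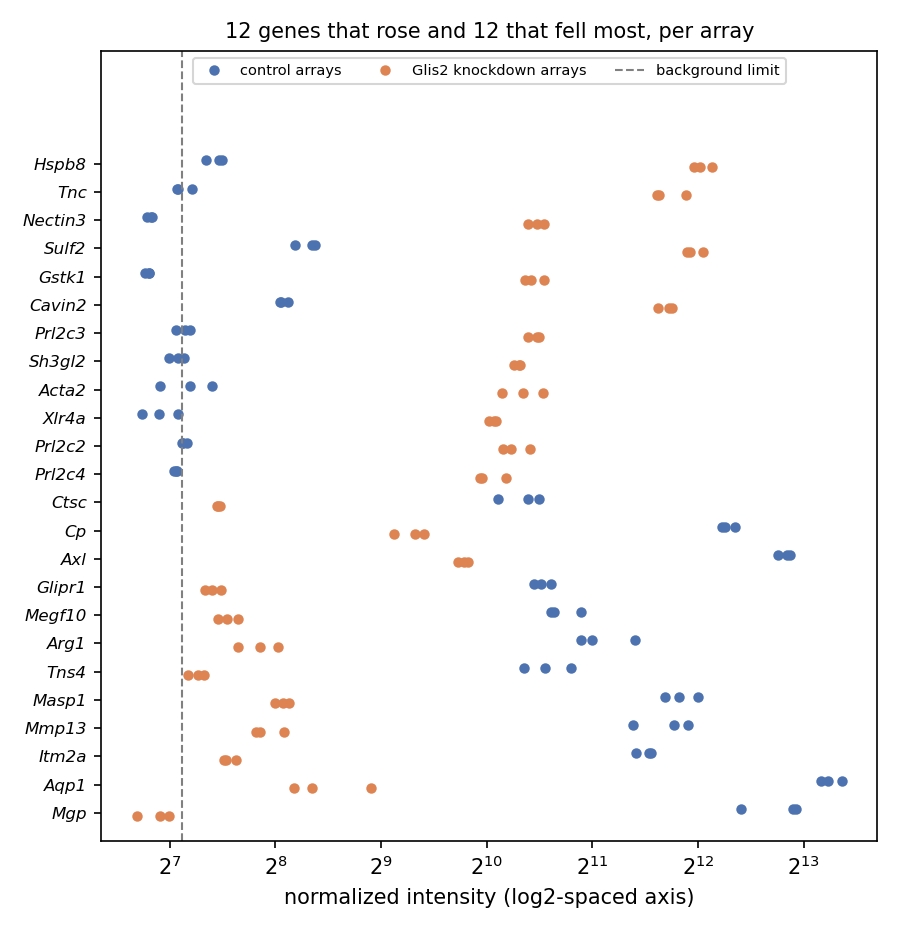
Intensity per array (log2-spaced x axis, linear units) of the 12 genes that rose and the 12 that fell most in the knockdown; blue points are 3 control and orange points 3 knockdown arrays, and the dashed line is the background limit of 139. The groups do not overlap for any gene shown, and Mgp, Nectin3, Gstk1, Xlr4a and Prl2c4 lie under the limit in 1 group.

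Chac1, Asns, Herpud1 and Trib3, of the unfolded protein and integrated stress response, were lower in the knockdown. Of 26 genes measured in that list, 11 fell, 1 rose and 14 were not called, or 13 fell and 1 rose adjusted over the list alone. Chac1, a glutathione-degrading enzyme, fell from 7739 ± 609 to 2891 ± 153, asparagine synthetase, Asns, from 18711 ± 1075 to 9587 ± 665, and Herpud1 and Trib3 had log2 fold changes of -0.89 and -1.29. The list was called lower by limma's camera with adjusted p = 0.00183 at the preset correlation and not with an estimated correlation, where the adjusted p = 0.360; over the alternatives with camera it ran from 0.000226 to 0.360. Hypoxia and glycolysis genes fell in 8 of 23 cases and rose in 2, or 9 and 2 adjusted over the list alone, with Pdk1, a kinase that inhibits pyruvate dehydrogenase, at -1.41, Vegfa at -1.36 and Ndrg1 at -0.91, while the glycolytic enzyme Pgam1 rose by 0.51. This list had limma's camera adjusted p = 0.0148, and the adjusted p = 0.360 with an estimated correlation. Keeping only probes above the median intensity gave it an adjusted p = 0.0537, and the alternatives with camera ran from 0.00726 to 0.360. Pgam1 lost its call with background subtracted and with normexp correction (limma's adjusted p = 0.143 and 0.0776).

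Interferon response genes fell in 11 of 32 cases and rose in 1. Ifit3, an interferon-induced gene, went from 589 ± 47.3 to 158 ± 9.68, Ifit2 from 961 ± 80.6 to 510 ± 67.9, and Stat2 had a log2 fold change of -0.69, while the guanylate-binding protein Gbp2 rose by 1.26 from 159 ± 24.3, under the background limit on 1 control array. The adjusted p was 0.0148 by limma's camera, and adjusted p = 0.390 with an estimated correlation, with 0.00958 the lowest of the alternatives with camera. Of 23 senescence and secretory factors, 7 fell and 3 rose. The members with the smallest p were Mmp13, the stromelysin Mmp10 at -2.51, Vegfa and the urokinase Plau at -1.31, all secreted proteins, whereas the cell cycle inhibitor Cdkn1a rose by 0.29. That list had limma's camera adjusted p = 0.0148, and adjusted p = 0.360 with an estimated correlation. Its adjusted p was 0.0577 with the mean of each gene's probes, 0.0996 with background subtracted and 0.0632 after normexp correction, within a range from 0.00437 to 0.360 over the alternatives with camera. By limma's camera 0 lists were called with an estimated correlation (3 at an unadjusted p under 0.05), against 4 with the preset one, whereas fry, which does not compare a list with other genes, called 20.

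In the extracellular matrix and fibrosis list 6 of 26 genes rose and 4 fell, or 7 and 5 adjusted over the list alone. Besides Tnc and Acta2, the collagen genes Col6a1, from 256 ± 17.2 to 1626 ± 17.5, and Col5a1, at least 3.79-fold, were higher. Limma's camera gave adjusted p = 0.195, and 0.0202 when genes in chromosome blocks were left out, within a range from 0.0202 to 0.416 over the alternatives with camera; fry, which tests against no change, gave 0.000475. Mesenchymal transition genes rose in 5 of 22 cases and fell in 5, or 6 and 5 adjusted over the list alone (camera adjusted p = 0.349, limma). Besides Acta2, Fbln1 was at least 1.70-fold and Myl9 at least 1.21-fold higher, and the transcription factor Twist2 had -0.62. Fbln1 lies in a block of higher genes on chromosome 15. Epithelial junction and keratin genes rose in 4 of 23 cases and fell in 6, with camera adjusted p = 0.599 in limma. The cadherin Cdh16, the claudin Cldn1 and the adhesion protein Cxadr had log2 fold changes of -1.41, -1.16 and -0.64, Cdh16 with 2 knockdown arrays under the background limit, and the keratin Krt8, which lies in another block of higher genes on chromosome 15, had 0.57.

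Proximal tubule genes fell in 3 of 21 cases and rose in 0, and 4 of the 21 were above background. Besides Aqp1 these were the membrane endopeptidase Mme, at least 6.11-fold lower, and the endocytic adaptor Dab2 at -0.46 (camera adjusted p = 0.4001, limma). Tubular injury genes rose in 5 of 17 cases and fell in 3, or 6 and 3 adjusted over the list alone. The member with the smallest p was Cp, given above, which fell with a log2 fold change of -2.99. The growth factor Hbegf rose by 1.36 although its neighbours on chromosome 18 had a median of -0.41, Krt20 rose by 0.63, and Timp1, an inhibitor of metalloproteinases in the X chromosome block, had -1.13 (camera adjusted p = 0.524, limma). Cilium and cystic kidney genes fell in 6 of 25 cases and rose in 1, or 8 and 1 adjusted over the list alone. Anks6, a protein of the nephronophthisis complex, rose from 203 ± 8.74 to 446 ± 24.9, and Iqcb1, Ift140 and Bbs2 had -0.48, -0.50 and -0.39 (camera adjusted p = 0.349, limma). Ift140 lost its call with the mean of its probes and with background subtracted (limma's adjusted p = 0.0588 and 0.0858).

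In the Hedgehog pathway and Gli family list 3 of 20 genes rose and 3 fell. Glis3, a paralog of Glis2, rose from 406 ± 21.7 to 678 ± 48.3, Ccnd1 rose by 0.38, Foxf1 had -0.34 and Ptch1 0.33 (camera adjusted p = 0.885, limma). The call of Ptch1 was lost without control replicate 2, control replicate 3 or knockdown replicate 3, with limma's adjusted p between 0.0538 and 0.119. It was also lost with the mean of its probes, background subtracted, normexp correction or relative to neighbouring genes (0.109 to 0.406), and that of Ccnd1 with normexp and relative to neighbours (0.0721 and 0.160). Wnt and beta-catenin targets rose in 6 of 23 cases and fell in 3, with Wnt4 at 1.19 and Myc at 0.53, while beta-catenin itself, Ctnnb1, fell from 16819 ± 2057 to 9260 ± 563 and Dkk3 was at least 1.15-fold lower (camera adjusted p = 0.314, limma). Targets of TGF-beta and SMAD signalling rose in 6 of 20 cases and fell in 3. The activin subunit Inhba, Id1 and Id3 rose by 1.69, 1.44 and 1.22, and Bmp4 had -1.82 (camera adjusted p = 0.177, limma). YAP and TEAD targets rose in 7 of 21 cases and fell in 5, with Ccn1 at 1.56, Rbms3 at least 3.15-fold higher and Nt5e at least 3.03-fold lower besides Axl (camera adjusted p = 0.842, limma).

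NF-kappaB and inflammation genes rose in 6 of 25 cases and fell in 5. The NF-kappaB inhibitor Tnfaip3 rose by 1.49, and Tnfaip2, the chemokine Cx3cl1 and Tslp had -2.04, -1.33 and -1.15, Tslp within a block of lower genes on chromosome 18 and under the background limit on 2 knockdown arrays (camera adjusted p = 0.842, limma). Apoptosis genes rose in 5 of 21 cases and fell in 6, or 6 and 7 adjusted over the list alone, with Cflar at 1.15, Casp9 at -0.77, Bid at -0.67 and Casp1 at least 1.37-fold lower (camera adjusted p = 0.945, limma). Targets of p53 rose in 6 of 24 cases and fell in 3, with Plk2 at 0.94, Apaf1 at 0.64 and Tnfrsf10b at 0.63 besides Sulf2 (camera adjusted p = 0.318, limma). Apaf1 lies in a block of higher genes on chromosome 10, and Tnfrsf10b lost its call with the mean of its 5 probes and with background subtracted (limma's adjusted p = 0.212 and 0.109).

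Mitosis genes fell in 7 of 23 cases and rose in 1. Nusap1, a spindle protein, fell from 5568 ± 25.3 to 2740 ± 219, and Top2a, Aurkb and Aurka had -0.61, -0.47 and -0.33 (camera adjusted p = 0.143, limma). Those 3 lost their calls with normexp correction (limma's adjusted p = 0.0514, 0.0567 and 0.108), and Top2a and Aurkb also with background subtracted (0.112 and 0.0648). DNA replication and E2F targets rose in 6 of 24 cases and fell in 4, or 6 and 6 adjusted over the list alone, with Fen1 at 0.58, Cdc45 at 0.45, Ccne1 at 0.37 and Cdt1 at -0.45 (camera adjusted p = 0.599, limma). Without knockdown replicate 3 the adjusted p of Ccne1 by limma was 0.0778, and relative to neighbours it was 0.269. Fen1, Cdt1, Cdc45 and Ccne1 lost their calls with background subtracted (0.0710 to 0.173 by limma's adjusted p), and the last 3 with normexp (0.0648 to 0.101). DNA damage genes fell in 4 of 25 cases and rose in 1, or 3 and 1 adjusted over the list alone, with Msh6 at -0.74, Atm at -0.66, Rad50 at -0.47 and H2ax at 0.28 (camera adjusted p = 0.488, limma). H2ax lost its call without control replicate 1, control replicate 2 or knockdown replicate 2, at limma's adjusted p between 0.0538 and 0.107. With background subtracted H2ax and Rad50 had limma's adjusted p = 0.0529 and 0.103, with normexp 0.168 and 0.0724, and Rad50 had 0.104 with the mean of its probes.

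Oxidative phosphorylation genes fell in 10 of 27 cases and rose in 1, or 11 and 4 adjusted over the list alone, with camera adjusted p = 0.177 in limma. Ndufa1 (-1.25) lies in the X chromosome block and Atp5a1 (-0.65) in a block of lower genes on chromosome 18, and Cox7a2 and Cox4i1 had -0.47 and -0.35. Atp5a1 lost its call with background subtracted, with normexp and relative to neighbours (limma's adjusted p 0.0507 to 0.123), and Cox4i1 with normexp (0.0914). Cholesterol synthesis genes fell in 6 of 18 cases and rose in 1, with Ebp in the X chromosome block at -1.14, Stard4 on chromosome 18 at -0.87, Sqle at -0.38 and Nsdhl at -0.33 (camera adjusted p = 0.177, limma). Sqle and Nsdhl lost their calls with normexp (limma's adjusted p = 0.0896 and 0.0796), Sqle also with the mean of its probes (0.0653) and Nsdhl relative to neighbours (0.140). NRF2 antioxidant genes fell in 6 of 22 cases and rose in 2, or 9 and 3 adjusted over the list alone, with the cystine transporter Slc7a11 at -1.26, Gstm1 at -0.94, catalase, Cat, at -0.81 and Gsta4 at -0.64 (camera adjusted p = 0.177, limma). Cytosolic ribosomal protein genes fell in 3 of 24 cases and rose in 1, or 2 and 1 adjusted over the list alone, with Rps24 at -0.34, Rpl22 at -0.33, Rps16 at 0.27 and Rpl4 at -0.26 (camera adjusted p = 0.599, limma). Rpl22 lost its call without control replicate 1 (limma's adjusted p = 0.0696). Rps16 lost it without control replicate 1, knockdown replicate 1 or knockdown replicate 3 (0.0909 to 0.138), and Rpl4 without any array other than control replicate 3 (0.0513 to 0.284). All 4 lost their calls with normexp (limma's adjusted p 0.108 to 0.249), the 3 besides Rps24 with background subtracted (0.0738 to 0.177), the 3 besides Rpl22 relative to neighbours (0.0634 to 0.502), Rps24 and Rpl4 with the mean of probes (0.182 and 0.0986), and Rpl4 with trend and robust settings (0.0522).

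Markers of other kidney cell types were mostly close to background, with 3 of 19 fibroblast, 6 of 20 distal nephron, 2 of 17 endothelial, 1 of 16 immune and 6 of 10 podocyte markers above it. Fibroblast and pericyte markers fell in 2 of 19 cases and rose in 1, with Dcn at -0.98 and Gsn at -0.88 (camera adjusted p = 0.599, limma). Dcn lies among higher genes on chromosome 10 and was under the limit on 2 knockdown arrays. Col1a2 went from 112 ± 9.16 to 135 ± 6.34, under the background limit on 3 control and 2 knockdown arrays, and lost its call without control replicate 1, control replicate 2, knockdown replicate 2 or knockdown replicate 3 (limma's adjusted p between 0.0777 and 0.183). Distal nephron markers rose in 1 of 20 cases and fell in 1, with Hsd11b2 at least 1.42-fold higher and Trpm6 at -0.31 (camera adjusted p = 0.599, limma). Trpm6 lost its call without control replicate 2, knockdown replicate 2 or knockdown replicate 3 (limma's adjusted p 0.0555 to 0.0873). Of 17 endothelial markers 1, Egfl7, rose, by 0.46 (camera adjusted p = 0.527, limma). Of 16 immune cell markers, Csf1r rose by 0.44 and Laptm5 was at least 1.25-fold lower (camera adjusted p = 0.599, limma). Podocyte markers rose in 4 of 10 cases and fell in 0, with the cell cycle inhibitor Cdkn1c at 1.11, Synpo at 0.42, Podxl at 0.39 and Actn4 at 0.32 (camera adjusted p = 0.112, limma). Csf1r and Synpo lie in a block of lower genes on chromosome 18. Actn4 lost its call without control replicate 3 or knockdown replicate 2 (limma's adjusted p = 0.0541 and 0.0523). Trpm6, Col1a2, Csf1r and Actn4 lost their calls with background subtracted (limma's adjusted p 0.0709 to 0.449) and with normexp (0.0510 to 0.142), Trpm6 and Synpo with the mean of probes (0.351 and 0.127), Col1a2 with an offset of 50 (0.0606), and Actn4 relative to neighbours (0.205). The median, the mean and the camera direction differed in sign for 6 lists, namely epithelial junctions and keratins, proximal tubule, tubular injury, YAP and TEAD targets, apoptosis, and fibroblast and pericyte markers. Adjusted over the list alone, 17 of the 29 lists had the counts given above.

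**Figure D3:**
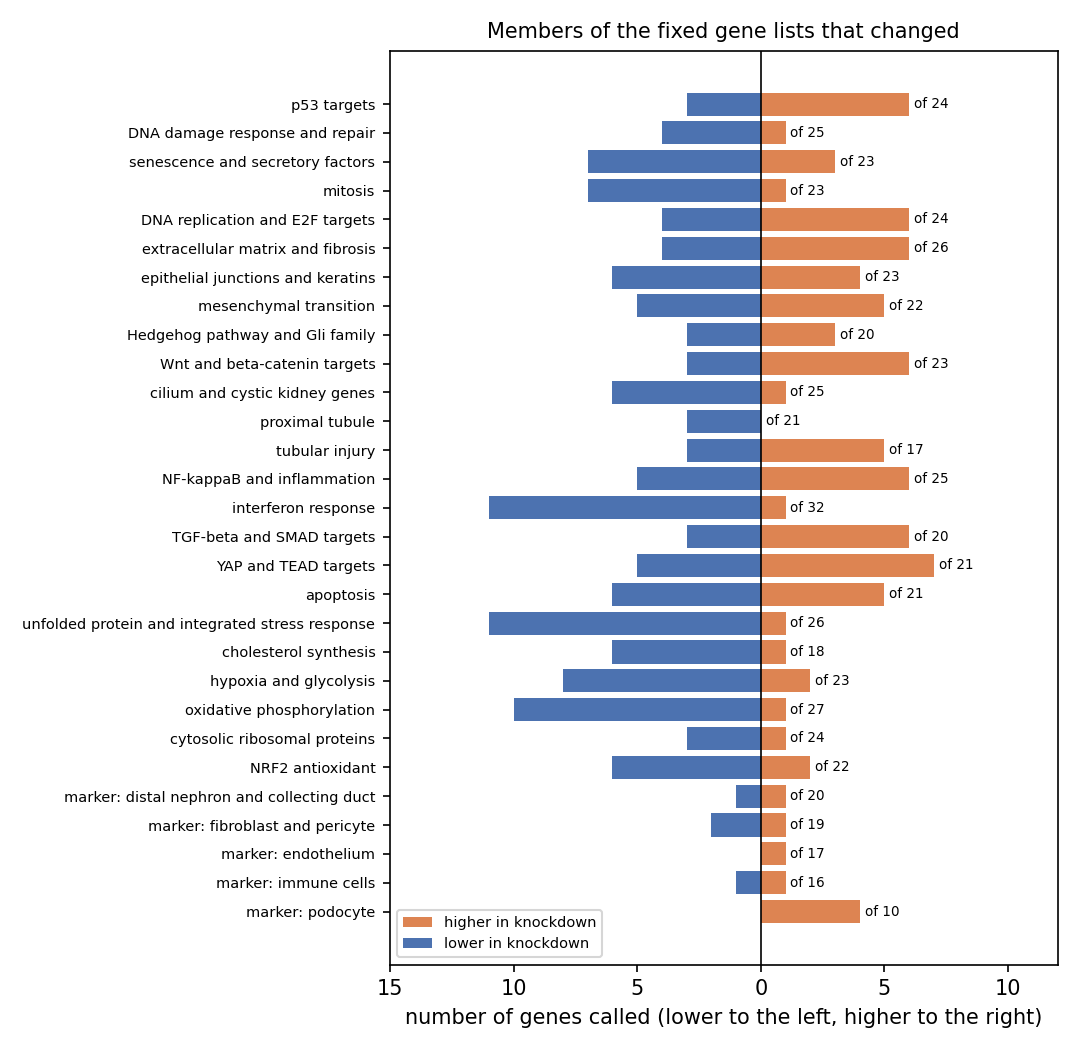
Number of genes called higher (orange, right) and lower (blue, left) in the knockdown for each of 29 gene lists, with the number measured beside each bar. Lower calls outnumber higher ones 11 to 1 among interferon response genes and 11 to 1 among unfolded protein and integrated stress response genes.

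Changes were also arranged along the chromosomes, which was examined after the data had been seen. On the X chromosome, 101 neighbouring genes above background from Vamp7 to Fgf13 in the gene order of assembly GRCm38.p6 had a median log2 fold change of -0.70, with 77 lower and 1 higher. Chromosome 18 held 227 genes with a median of -0.33, and the whole X chromosome one of -0.22, while chromosomes 19, 10 and 7 had medians of 0.23, 0.20 and 0.16. In 11 of 20 chromosomes, which also included 5, 6, 9, 12, 13 and 15, the absolute median lay above 0.079, the highest over 1000 shuffled orders. Windows of 25 genes passed the 95th percentile of the shuffled maxima, 0.389, in 12 blocks on chromosomes 1, 7, 10, 15, 18, 19 and X. The highest shuffled maximum was 0.462, and no window in the blocks on chromosomes 1, 7 and 19 passed it. Nor did any in the block from Polr2e on chromosome 10 or that from Cers5 on chromosome 15. The block on chromosome 1 reached 0.3887 against a limit of 0.3885. The 12 blocks held 589 genes, or 6.24% of the genes placed and above background, and 389 of them were called. That is 9.41% of the called genes placed and above background. Of the genes in blocks 66.0% were called, against 42.3% of those outside. The blocks were picked by these same fold changes, so a higher share inside them follows from that choice and is not a separate result.

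**Figure D4:**
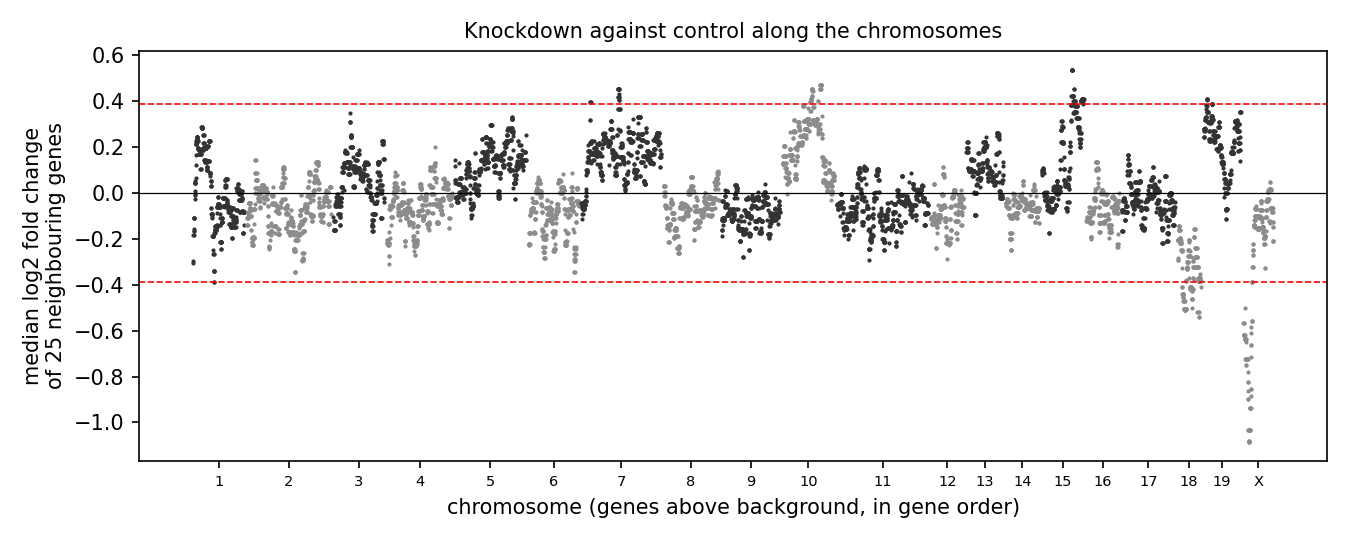
Median log2 fold change (knockdown against control, y axis) of 25 neighbouring genes above background, in gene order along chromosomes 1 to 19 and X (x axis); red dashed lines mark 0.389 above and below 0. The lowest window, on the X chromosome, is at -1.09, and the highest, on chromosome 15, at 0.54.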

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

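Probes without a single gene symbol in the annotation were left out of the comparison of genes, and 461 of these 10396 probes were higher in the knockdown than in the control by limma, while 471 were lower. The probe with the highest log2 fold change was ILMN_1230991, from 1755 ± 85.4 in control to 7555 ± 220 in knockdown cells (SD, n = 3), and the lowest was that of ILMN_2807016, from 2704 ± 294 to 556 ± 25.6. Their genes are not named here.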

How the results depend on the processing

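Alternatives using background subtraction, normexp, neighbouring genes or the removal of block genes were chosen after seeing the data. Of 4290 called genes (2124 higher, 2166 lower), a doubling or a fall to 50% kept 418 (189 and 229; 424 and 466 with the most frequent value subtracted, 331 and 372 with normexp, 133 and 139 with the mean of probes), and counting all probes gave 7065 (3549 and 3516), since more features were counted. Subtracting the most frequent value gave 2631 (1308 and 1323), and normexp 2566 (1265 and 1301); the cause was not tested. Leaving out 1 array gave 3751 to 3994 calls (1862 to 1964 higher, 1889 to 2030 lower), Glis2 between -0.60 and -0.46, and 4 lists throughout. The other count alternatives stayed between 3282 and 4365; median centring and a floor of 32 changed no count. The replicate block gave 4119 calls, 4087 of them shared in direction with the 4290, and Glis2 at -0.55; Rpl4 had limma's adjusted p = 0.0712 with it. Deviations of same-numbered arrays correlated at -0.097, -0.040 and -0.043, and no control array correlated best with its own number, so the numbers are not read as pairs.

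Lists called numbered 4, against 0 with an estimated correlation, 20 with fry, 3 under mode subtraction, normexp, the mean of probes or the median filter, and 5 without block genes; the cause was not tested. Test directions turned for the Hedgehog list without control replicate 3 (mean 0.012; 0.036 without control replicate 1 was the highest), with the mean of probes (-0.015), with normexp (-0.027) and relative to neighbours (-0.0030). They also turned for apoptosis without control replicate 3 (0.016; -0.0074 without control replicate 1 was the lowest) and with fry (0.0044), for tubular injury with fry (-0.037), for NF-kappaB relative to neighbours (-0.060), and for YAP with fry (-0.033) and without block genes (-0.076). Of these only YAP under fry was called (limma's adjusted p = 0.0306 against no change; the alternatives with camera gave 0.681 to 0.961). Of 122 named genes other than Glis2, 0 changed direction under the alternatives run for them and 27 lost their call under at least 1, 26 of them under mode subtraction or normexp and 9 without 1 array. The genes that lost calls with normexp included bright ones such as Rps24 and Ccnd1, and the cause was not tested. Signal over background limits folds against groups under the background limit, which are given as bounds only where all 3 arrays lay under it.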

Other observations

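The tests of families, chromosome blocks, neighbouring genes, fibroblast transcripts and Xist were chosen after the result was seen, whereas the count of called genes, the splits and the camera test of the matrix list were chosen earlier. Genes sharing a symbol stem were compared with all genes above background, over 278 tests of 139 families, by a hypergeometric test with Benjamini-Hochberg adjustment. Mitochondrial ribosomal protein genes with the stem Mrpl rose in 20 of 45 cases and fell in 3, with Mrpl11 from 1153 to 2237 and Mrpl36 from 2205 to 4109. Those with the stem Mrps rose in 11 of 27 cases and fell in 0, and were not called (hypergeometric adjusted p = 0.434). RNA polymerase subunit genes (Polr) rose in 11 of 19 cases and fell in 0, with Polr1b at a log2 fold change of 0.72 and Polr2j at 0.63. Genes of ATPases and ATP synthase (Atp) fell in 23 of 52 cases and rose in 7, among them the subunits of the proton pump that acidifies lysosomes Atp6v1h at -1.04 and Atp6v1a at -0.79. Keratin genes (Krt) rose in 9 of 13 cases and fell in 1, with Krt14 at least 2.33-fold higher, Krt13 at least 1.96-fold lower and Krt10 at 0.70. The limit was applied to the mean over all 6 arrays, which can favour dim genes that changed. Krt14 and Krt17, with control means of 123 and 138, passed it only through their knockdown values, and Krt13 only through its control values. The hypergeometric test takes genes as independent draws, although members of a family may vary together. Its adjusted p was 0.0416 for each of the 4 called families, Mrpl, Polr, Atp and Krt. Relative to the 50 neighbouring genes these families were not called, with 19 Mrpl genes higher and 2 lower (adjusted p = 0.0973), 9 Polr genes higher and 0 lower (0.375), 18 Atp genes lower and 4 higher (0.396), and 7 Krt genes higher and 2 lower (0.375). Those counts moved little for Mrpl, and the lost calls do not show that neighbouring genes were the cause.

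The same search over all tested genes, run first, had 315 families and called 6, of which Mrpl, Atp and Polr were also called above background. The others were Rad (9 of 17 lower), Rrp (6 of 8 higher) and Mrps (11 of 28 higher), and Krt had an adjusted p of 0.634. The tested keratin genes were 49 in that search (10 higher) and 13 above background, so members, background and number of families all differed, and which of these moved the outcome was not tested.

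Neighbouring genes changed together along the chromosomes, with a rank correlation of 0.219 between their log2 fold changes across genes, which are not independent replicates, above the 0.0323 that was the highest of 1000 shuffled orders. Against a trend with probe intensity, genes of the same intensity on other chromosomes had a median of at least -0.10 in 1000 draws, where the X chromosome block had -0.70, and against variation between single arrays, no array deviated from its own group by more than 0.124 over 25 genes. When the X chromosome block was found on every second gene, 92.3% of the 52 genes in between were lower. The share was the same in the brighter and the dimmer part, with medians of -1.08 and -0.34. These genes lie in a block already seen on the same arrays, where 93.1% of 101 genes were lower. The share thus restates the block, and any regional cause would give it. A difference in copy number between the cell populations may account for the block, but this test cannot single it out. In the same test on chromosomes 5, 7, 10, 15, 18 and 19 the shares were 70.8% to 84.0%. They were 75% to 92% in the brighter and 66.7% to 76% in the dimmer part. The block on chromosome 1 was not found again while 1 on chromosome 5 was added, and copy number stays open there too. Regional silencing without loss of DNA cannot be told apart from a copy number difference in the X block. RNA alone gives the median of -0.70 in both cases. Whether the hairpin or a difference between the populations that arose otherwise lies behind the X block was not tested.

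The number of called genes, 4290, was the result for 1 of the 10 splits of the 6 arrays, and the highest of the others was 0 by limma, with at most 524 genes at an unadjusted p under 0.05. The splits are too few for a share under 0.05. Removing the median of 50 neighbours, done only for placed genes above background, left 3971 genes called by limma. Of these, 3331 were shared in direction with the 4290. The chromosome blocks held 9.41% of the called genes placed and above background, so most calls lay outside them from the start. The neighbour median was also removed from genes outside the blocks. Some of the 4290 calls were lost and others were new, so the count of 3971 does not give the part of the blocks. A difference between the cell populations could change genes outside the blocks too, and was not tested.

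Acta2, Tnc and Col6a1 were higher in the knockdown, while the extracellular matrix and fibrosis list as a whole was not called by limma's camera (adjusted p = 0.195). Fibroblasts mixed into those samples would bring their abundant transcripts, but Col1a1, Col1a2, Col3a1, Dcn and Lum, all from the marker list, had a median knockdown intensity of 126, under the background limit of 139. Among them Col1a2 was called higher (0.26), Dcn lower (-0.98), and the others were not called. Intensities this close to background argue against a large share of fibroblasts but cannot exclude a small one. No other technical explanation was tested for this pattern. Nor was a difference between the cell populations that arose otherwise, and a response to the knockdown stays possible as a hypothesis.

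Xist, the RNA that silences an X chromosome, went from 3656 ± 375 to 1356 ± 41.4 (SD, n = 3), with limma's adjusted p = 2.13e-11. It was singled out after its value was seen.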
